A study of Mus musculus with 36 samples.

How the data were processed

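The ATAC-seq part of the series holds 6 libraries, 1 sham and 1 border zone library for each of days 4, 7 and 14 after surgery. Per the labels' protocols, nuclei of day 4 were enriched by a PCM1 pulldown and sequenced with paired reads of 76 bp. For days 7 and 14, 50000 reporter-positive nuclei per sample were sorted by flow cytometry from mice that had received tamoxifen at 20 mg/kg. Per the submitters' processing notes, reads were aligned to mm9 with Bowtie2 for day 4 and with BWA for days 7 and 14, and bedtools was used on all days. Tool versions, the region caller, its thresholds and the handling of duplicate reads or of the transposase offset are not given in the sources used here. The isolation of nuclei and the aligner therefore change together with the day between day 4 and the later days. The 30 RNA-seq samples of the series were not analysed here.

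Per the file headers, each of the 9 deposited lists gives a region, its sham tags and its border zone tags. The sham tags are deposited counts, whole numbers in every list. The border zone tags are a deposited signal, which the authors scaled to the sham library, except in the non-differential list of day 4, where they are counts per the file headers and left unscaled. The scaling was read from the values. In the other 8 lists, 97.6% of the 85106 border zone values were a whole number times 1 of the day's few factors, within a relative tolerance of 0.001%. Another 1974 values were sums of such terms, and 29 could be brought back to tags only approximately. The factors were 1, 1.03 and 1.10 on day 4, 1.17 and 1.35 on day 7, and 1.18 and 1.37 on day 14. The regions with these factors had a median of 45, 60 and 103 tags in total on day 4, 65 and 92 on day 7, and 255 and 251 on day 14. Listed folds are of the scaled values, and whole tags were recovered for checks of depth, counting noise and scaling. Region starts lie 500 bp apart or multiples of it, and the median width in every list was 1000 bp.

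Every differential region had a fold of at least 1.75 between the listed values, and the larger value was at least 35, 50 and 150 tags on days 4, 7 and 14. Regions with fewer tags appear in none of the lists, so a missing region has no measured value. The tags of listed regions are part of each library, and the depth of the libraries is unknown here. Tags without molecular identifiers are not independent molecules, and all intervals and noise estimates cover counting error only.

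Each list was assigned to its samples through the column names and labels, and 0 columns of unmapped samples were used. With 1 library per condition and day there was no test within a day or between days, and regions were not treated as replicates. Regions of different days that overlapped by at least 1 bp were joined into loci, and a locus was called for a direction on a day when it held a differential region of that direction and none of the other on that day. Its tags are summed over all its regions of the day, non-differential ones included. Shared loci were compared with the number expected from loci of matched width and with 10000 random sets. Agreement of direction was compared with the share expected from the frequencies of both directions. Neighbours within 50 kb were compared with 1000 permutations of direction among the differential regions of a day, and the lowest and highest permuted shares are given. Shares have exact Clopper-Pearson 95% intervals, and the interval of a fold comes from the exact interval of the border zone share of whole tags. The number of calls expected from counting noise took each listed region's tags as fixed and split them between the libraries by chance. Regions missing from the lists did not enter it.

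The conditions were compared over the 3 days in the 19733 loci listed on all of them, with whole tags summed per locus, the few approximate ones rounded. The sham and border zone libraries of a day form a pair by day. edgeR was run with TMM normalization and its quasi-likelihood test on a model of day and condition, which leaves 2 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method. These p-values measure the spread between these libraries. The spread includes differences of the effect between days, and nothing in the sources used here says whether the libraries came from separate animals. The SE given with a log2 fold change is its absolute value divided by the square root of the test's F statistic. This test, its settings and the same model in DESeq2 were chosen after the data were seen.

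Windows were named by a rule set before the data were examined. On a fixed grid of 100 kb, these were the 5 windows per direction with the largest difference between the numbers of border zone-higher and sham-higher regions over the 3 days and with that direction on every day. The 3 loci per direction named by their smallest fold were chosen after the data were seen. Coordinates are mm9, counted from 1.

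The planned promoter shares, gene lists, named genes and motif shares need an mm9 annotation or sequence and were not run. The gene tables at hand are for GRCm38.p6, and coordinates were not converted between builds. The alternatives set before the data were examined were other overlap rules, stricter lists, merged regions, covered length, other neighbour distances and other windows. For the stricter list, regions in the upper part of the day's tags, from the median upward, were used in place of a width limit, because the median width equalled the smallest common width. Alternatives added after the data were seen were 1 scaling factor per day, a fold of at least 2, an expectation matched on tags, and leaving out chromosome Y and unplaced contigs.

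The steps were tested on simulated data. In 41526 simulated loci for days 4 and 7 all simulated shared loci were recovered, 1200 for the border zone, 600 for sham and 200 in opposite directions. In a simulation of day 4 with its 46827 listed regions, all 200 changed regions, each with a 3-fold change and over 200 tags, were called. Without any change the expected calls averaged 334.7 against 332.1 simulated. This simulation does not cover regions missing from the lists. For the test over the 3 days, all 200 simulated loci with a 3-fold change were recovered, with 2 false calls among 19733 loci. The simulated change was the same on every day, so this does not cover effects that differ between days. Calculations used R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.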

Results

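Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in cardiomyocyte nuclei from the left ventricle of FVB/N mice. Nuclei came from the border zone, the surviving muscle beside the scar of a myocardial infarction, and from the ventricle of sham-operated animals. There was 1 sham and 1 border zone library on each of days 4, 7 and 14 after surgery, which makes 6 libraries and leaves no replicate of a condition within a day. Comparisons within a day and between days therefore describe these libraries and were not tested. The conditions were tested over the 3 days together, with day as a block. Intervals below are exact 95% binomial intervals of tag or region counts, and they cover counting error only. The nuclei of day 4 were enriched with an antibody to PCM1, a protein found around cardiomyocyte nuclei, whereas those of days 7 and 14 were sorted by a genetic cardiomyocyte reporter. Day 4 and the later days therefore also differ in how the nuclei were obtained. A further 30 samples of the series were RNA-seq libraries of sham, remote, border and infarct zone tissue and were not analysed here.

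For each day, 3 deposited lists gave the regions with more tags in the border zone, those with more tags in sham and those that did not differ. They held 46827 regions on day 4, 34952 on day 7 and 40980 on day 14. The listed regions carried 5907384 sham and 5470550 border zone tags on day 4, 3858892 and 2743793 on day 7, and 13936013 and 10334810 on day 14. These sums cover listed regions and are not the depth of the libraries. Regions are given by their mm9 coordinates. The genes at these positions were not assigned, because no mm9 annotation was used here.

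The first comparison asked where border zone chromatin differed from sham on each day. On day 4, 5721 regions had more tags in the border zone and 3453 had more in sham. On day 14 the same direction prevailed, with 5501 regions higher in the border zone and 2765 higher in sham. On day 7, 6120 regions were higher in the border zone and 7704 were higher in sham. The border zone share of differential regions was thus 62.4% on day 4 (61.4 to 63.4%), 44.3% on day 7 (43.4 to 45.1%) and 66.5% on day 14 (65.5 to 67.6%). Differential regions made up 19.6% of listed regions on day 4, 39.6% on day 7 and 20.2% on day 14.

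The border zone tags of the lists are scaled, and a larger factor raises the border zone share by construction. With 1 median factor per day applied to the whole tags, the regions of day 7 split into 7342 higher in the border zone and 5661 higher in sham, a border zone share of 56.5%. With 1 factor per day from the listed tags they split into 6608 and 6839, a share of 49.1%. The shares were 63.8% and 65.7% on day 4 and 62.9% and 65% on day 14 with these 2 factors. Both were chosen after the data were seen, and which factor is right is not known, so the side of 50% on which day 7 lies stays open.

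**Figure D1:**
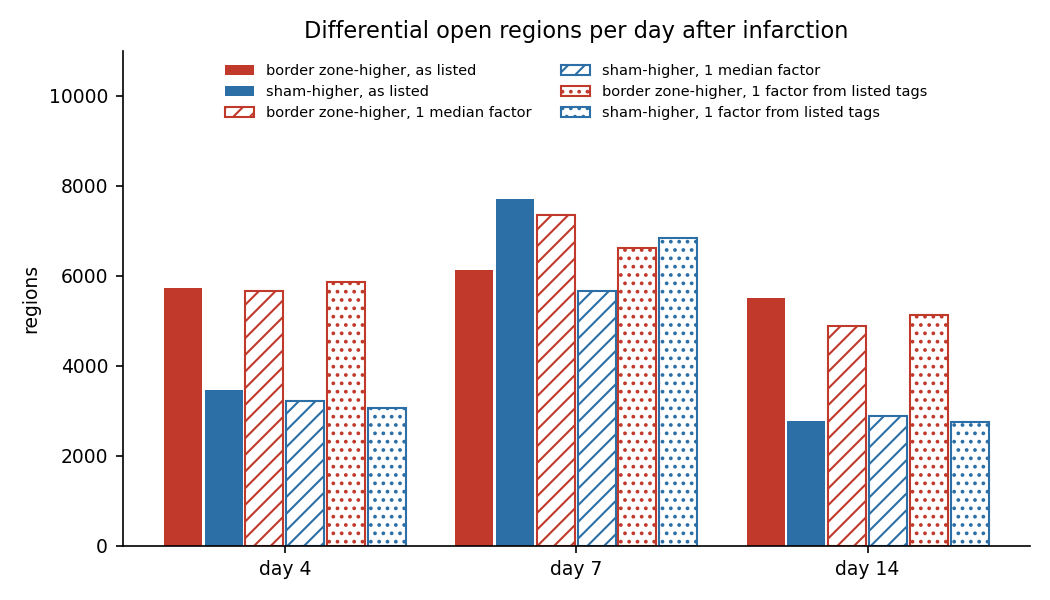
Bars give the number of regions (y axis) with more tags in the border zone (red) or in sham (blue) on each day (x axis), as listed (filled), with 1 median scaling factor per day (hatched) and with 1 factor per day from the listed tags (dotted), with 1 library per condition and day. Sham-higher regions outnumber border zone-higher regions on day 7 as listed, 7704 against 6120, and the numbers are 5661 against 7342 with the median factor and 6839 against 6608 with the factor from listed tags.

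Most differences were about 2-fold. The median fold of border zone-higher regions was 2.12 on day 4, 2.24 on day 7 and 2.11 on day 14, and that of sham-higher regions was 1.98, 2.14 and 1.95. At least 4-fold differences were found in 401, 543 and 168 border zone-higher regions on days 4, 7 and 14, against 52, 144 and 11 sham-higher regions. Every listed difference was at least 1.75-fold, and the larger tag value was at least 35 on day 4, 50 on day 7 and 150 on day 14. Counting noise alone was estimated for the listed regions, with equal accessibility in both libraries and each region's tags as fixed. It would be expected to give 357 of the 9174 calls on day 4 and 225 of the 13824 calls on day 7. On day 14 it would give 0.34 of the 8266 calls. Balanced regions with as few tags were not listed and are missing from this estimate, so it can be too low. Calls of both directions were most frequent among regions with the fewest tags. The tag minimum applied to the larger value, so a region with a low total could be listed only if its values differed. In the lowest 10% of regions by tags, 44.4% on day 4, 47.4% on day 7 and 59.4% on day 14 were border zone-higher, and in the highest 10% 0.384%, 7.09% and 2.81% were. Sham-higher regions made up 33.7%, 35.3% and 10.5% of the lowest 10% and 0.192%, 15.2% and 2.88% of the highest. Regions were ranked by whole tags, whereas the minimum applied to the listed values, with border zone tags scaled up. A border zone-higher region could therefore be listed with fewer whole tags than a sham-higher one. This raises the border zone share of the lowest 10% by construction.

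Of the 5 windows of 100 kb with the most border zone-higher over sham-higher regions and the border zone ahead on all 3 days, 3 lay on chromosome 5. The windows at 14900001 to 15000000, 15000001 to 15100000 and 15100001 to 15200000 of chromosome 5 held 30, 24 and 30 border zone-higher regions over the 3 days and 0 sham-higher regions. In the window from 14900001, tags of its 14 border zone-higher regions were 2.07-fold higher in the border zone on day 7 (1.98 to 2.17), and those of its 15 on day 14 were 2.33-fold higher (2.23 to 2.43). The neighbouring window from 15000001 gave 2.08-fold on day 7 (1.97 to 2.21) in 11 regions and 2.39-fold on day 14 (2.27 to 2.51) in 12 regions. The window from 15100001 gave 2.11-fold (2.0 to 2.21) and 2.36-fold (2.25 to 2.47) in 12 and 14 regions. The other named windows were 19900001 to 20000000 of chromosome 8, with 26 border zone-higher regions over the 3 days, 16 of them on day 7 and 7 on day 14, and 47600001 to 47700000 of chromosome 6, with 24, of which 9 and 14 on these days. Both held 0 sham-higher regions. The tags of their border zone-higher regions were 2.14-fold and 2.19-fold higher on chromosome 8, and 1.97-fold and 2.07-fold higher on chromosome 6. The folds of all 5 windows leave out non-differential regions. On days 7 and 14 these numbered 11 and 7 on chromosome 8 and 10 and 13 on chromosome 6. In the chromosome 5 windows from 14900001, 15000001 and 15100001 they numbered 10 and 0, 5 and 2, and 8 and 3. On day 4 these 5 windows held only 1, 1, 4, 3 and 1 border zone-higher regions in the order given, so their direction on that day rests on few regions. Whether these windows hold repeated sequence, where reads map to several places, was not examined.

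Sham-higher regions clustered most densely at 122900001 to 123000000 of chromosome 5, with 30 sham-higher regions over the 3 days and 1 border zone-higher region. Sham tags of the sham-higher regions there were 1.94-fold higher on day 4 (1.74 to 2.16; 10 regions), 2.59-fold on day 7 (2.49 to 2.69; 5 regions) and 1.94-fold on day 14 (1.87 to 2.01; 15 regions). On day 7 one of these regions spanned 41.0 kb, from 122909751 to 122950750, with 7673 sham tags against 2882 scaled border zone tags; it was singled out after its values were seen. A pair of adjoining windows on chromosome 2, from 76600001 to 76700000 and from 76700001 to 76800000, held 22 and 20 sham-higher regions and 0 and 1 border zone-higher regions. In the first of them sham was 2.12-fold higher on day 4 (1.58 to 2.86), 2.28-fold on day 7 (2.10 to 2.47) and 1.95-fold on day 14 (1.82 to 2.09), and in the other it was 1.99-fold (1.66 to 2.38), 2.30-fold (2.20 to 2.41) and 1.94-fold higher (1.79 to 2.11). These folds rest on 3, 13 and 6 sham-higher regions in the first window and 4, 13 and 3 in the other, beside 24, 6 and 19 and 16, 6 and 17 non-differential regions that they leave out, so on day 4 they rest on few regions. The window at 55500001 to 55600000 of chromosome 14 had 16 sham-higher and 0 border zone-higher regions, with sham 1.95-fold higher on day 4 (1.84 to 2.07), 2.5-fold on day 7 (2.04 to 3.07) and 2.35-fold on day 14 (2.29 to 2.41), from 7, 2 and 7 regions. On day 14 the median log2 ratio of border zone to sham over the 7 regions was -0.89, a weaker difference than that of their summed tags. At 104500001 to 104600000 of chromosome 12, 17 regions were sham-higher and 1 was border zone-higher, and the folds were 1.83, 2.44 and 1.85, from 4, 7 and 6 regions. Across the genome, 545 windows had the border zone ahead on all 3 days and 249 had sham ahead. The folds of these windows are over regions already called in that direction.

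**Figure D2:**
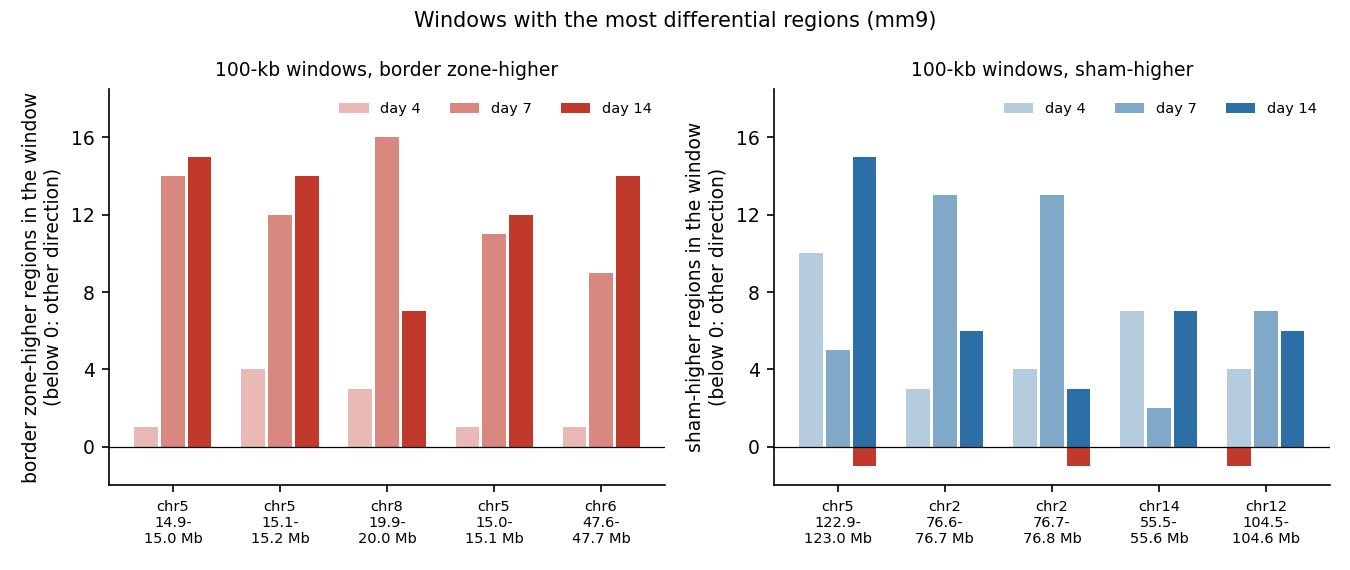
Bars give the number of differential regions (y axis) in each of the 5 windows of 100 kb named per direction (x axis, mm9 position in Mb) on days 4, 7 and 14, from light to dark, and bars below 0 count regions of the other direction. The border zone windows hold 1 to 4 border zone-higher regions on day 4 and 7 to 16 on the later days, and the sham windows hold 2 to 15 sham-higher regions on each day.

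Within 50 kb, differential regions of one direction lay near each other more often than permuted directions gave on days 4 and 7, and on day 14 this held for the border zone. On day 14, 57.9% of border zone-higher regions had another within 50 kb, against 43.0 to 47.2% over 1000 permutations of direction. The shares were 45.6% against 38.5 to 42.3% on day 4 and 52.8% against 45.0 to 49.1% on day 7. Of sham-higher regions, 32.1% on day 4 (25.6 to 31.0% permuted) and 61.2% on day 7 (51.6 to 55.3%) had a sham-higher neighbour. On day 14 the share was 27.7%, inside the permuted range of 25 to 32.0%. Within 200 kb, 2 further shares lay inside the permuted range, 79.1% of border zone-higher regions on day 7 (75.8 to 79.8%) and 63.2% of sham-higher regions on day 4 (57.5 to 63.2%).

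The next comparison asked whether the same places differed on more than 1 day. Overlapping regions of different days were joined into loci. Border zone-higher loci recurred on every pair of days. Days 7 and 14 shared 2208 loci called for the border zone on both days, where 539 were expected for loci of matched width, a ratio of 4.10. Days 4 and 7 shared 605 against 138 expected, and days 4 and 14 shared 538 against 122, each a ratio of 4.40. Each observed number lay above all 10000 random sets, whose highest values were 611, 181 and 161. For days 4 and 7 and for days 4 and 14 the ratio was 2.87 and 3.16 with an expectation matched on tags, and 6.82 and 8.10 for regions with midpoints within 250 bp.

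Sham-higher loci recurred mainly between days 7 and 14, which shared 1308 against 445 expected, a ratio of 2.94. Days 4 and 7 shared 439 against 375 expected, and days 4 and 14 shared 172 against 128, ratios of 1.17 and 1.34. All 3 numbers exceeded the 10000 random sets, whose highest values were 513 for days 7 and 14, 436 for days 4 and 7 and 169 for days 4 and 14. The excess in both pairs with day 4 depended on the overlap rule together with the expectation. Regions with midpoints within 250 bp gave 150 shared on days 4 and 7, a ratio of 0.916 (0.791 to 1.05), and 69 on days 4 and 14, a ratio of 1.11 (0.870 to 1.38), and both numbers lay inside the random sets of matched width, whose highest values were 203 and 92. Against an expectation matched on tags, the same numbers gave ratios of 1.94 and 2.10, and those of regions overlapping by at least 1 bp gave 1.45 and 1.63.

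Of 3581 loci that differed on both day 7 and day 14, 98.2% had the same direction (97.7 to 98.6%), where 53.1% were expected from the share of each direction. Agreement with day 4 was lower. The same direction was found in 83.1% of 1257 loci on days 4 and 7 (80.9 to 85.1%, 50.8% expected) and in 84.2% of 843 loci on days 4 and 14 (81.6 to 86.6%, 59.2% expected). Over all loci listed on both days, differential or not, Spearman's correlation of the log2 ratio of border zone to sham was 0.77 for days 7 and 14, 0.32 for days 4 and 7 and 0.32 for days 4 and 14. These correlations are across loci, which are not independent replicates.

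**Figure D3:**
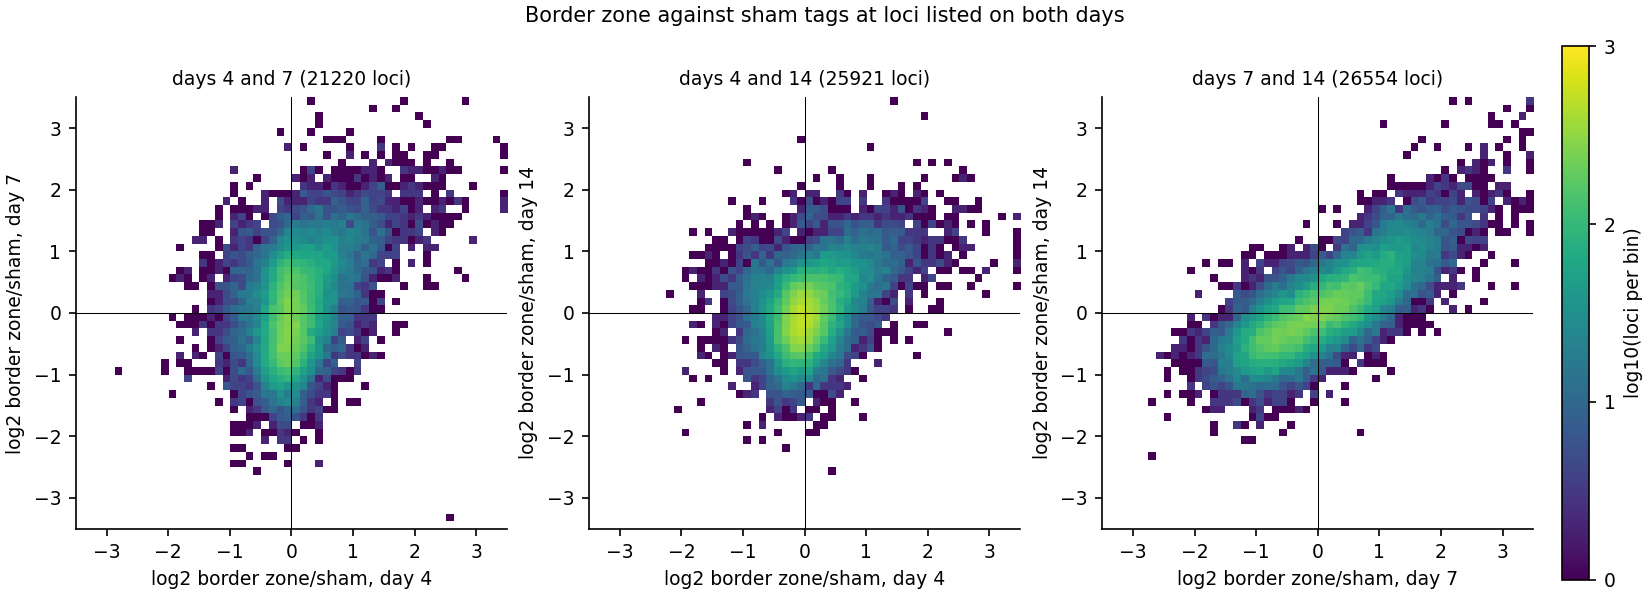
Each panel plots the log2 ratio of border zone to sham tags, centred on the day's median, at loci listed on both days (x axis, earlier day; y axis, later day), coloured by log10 of the loci per bin. The cloud of 26554 loci on days 7 and 14 lies along a diagonal (Spearman 0.77), and the clouds with day 4 follow it less closely (0.32 in both).

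Of 19733 loci listed on all 3 days, 297 were border zone-higher on every day, where the product of the daily shares gave 8.33, and 115 were sham-higher on every day, where it gave 27.4. A further 9533 differed on no day. The most frequent differential pattern was sham-higher on day 7 alone, with 4730 loci, followed by sham-higher on days 7 and 14 but not day 4, with 1140. With 1 median factor per day the first of these numbers was 3398, and with 1 factor from the listed tags it was 4188. Loci listed on all 3 days favour sham-higher regions of the later days, which were listed on day 4 more often than border zone-higher ones. Without the day 4 lists, 2208 loci were border zone-higher and 1308 sham-higher on both remaining days.

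Over the 3 days together, with day as a block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1516 of these 19733 loci higher in the border zone and 457 higher in sham at a false discovery rate of 5%. Of the 297 loci listed as border zone-higher on every day 291 were called, of the 115 listed as sham-higher 81 were called, and of the 9533 that differed on no day 167 were called for the border zone and 0 for sham. The lists and the test rest on the same tags, so these numbers are not independent support for the lists. The test also normalizes the libraries on these same loci, and the balance of the directions can depend on that choice. Without day 4 the test called 3073 loci for the border zone and 2140 for sham, without day 7 it called 950 and 128, and without day 14 551 and 20. DESeq2 with the same block called 1024 and 114. Without the block edgeR called 0 loci in either direction, with 584 at an unadjusted p under 0.05. The test was chosen after the data were seen and rests on 3 pairs of libraries, and whether each library came from separate animals is not given in the sources used here.

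The loci with the largest smallest fold over the 3 days were chosen after the data were seen. A locus at 25171751 to 25173250 of chromosome 7 was higher in the border zone by 5.54-fold on day 4 (3.77 to 8.37), 5.60-fold on day 7 (4.17 to 7.64) and 4.58-fold on day 14 (3.68 to 5.74). It had 32, 56 and 106 sham tags on these days. A locus at 26084251 to 26086750 of chromosome 8 followed with 4.56-fold (3.09 to 6.93), 4.58-fold (3.5 to 5.88) and 4.87-fold (4.06 to 5.87). At 8896251 to 8897250 of chromosome 18 the border zone was 4.97-fold, 4.17-fold and 4.20-fold higher, from only 10, 14 and 45 sham tags. On the sham-higher side, 54295251 to 54296750 of chromosome 4 was 2.27-fold (1.51 to 3.49), 2.47-fold (1.77 to 3.51) and 2.41-fold higher in sham (2.04 to 2.87). The next was 31027251 to 31029250 of chromosome 12, at 4.30-fold (3.00 to 6.31), 2.27-fold (1.65 to 3.16) and 3.15-fold (2.65 to 3.75). At 34569751 to 34571250 of chromosome 18 the folds in sham were 2.45, 2.53 and 2.09. In the edgeR test over the 3 days, log2 fold changes of border zone to sham with Benjamini-Hochberg adjusted p were 2.54 (SE 0.21, adjusted p = 9.88e-08) for the chromosome 7 locus, 2.44 (SE 0.20, adjusted p = 9.88e-08) for that of chromosome 8 and 2.36 (SE 0.30, adjusted p = 3.58e-05) for the first of chromosome 18. They were -1.09 (SE 0.20, adjusted p = 0.0012) for chromosome 4, -1.47 (SE 0.22, adjusted p = 0.000174) for chromosome 12 and -0.91 (SE 0.29, adjusted p = 0.0443) for the sham-higher locus of chromosome 18.

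Regions of the lists were also compared by whether another day listed them at all. Border zone-higher regions of the later days were among the listed regions of day 4 in a minority of cases, 31.9% of those of day 7 (30.7 to 33.1%) and 31.4% of those of day 14 (30.1 to 32.6%). Sham-higher regions of the later days were mostly listed on day 4, 91.0% of those of day 7 (90.3 to 91.6%) and 90.4% of those of day 14 (89.3 to 91.5%). Non-differential regions lay between, at 72.9% for day 7 and 72.5% for day 14. Between the later days the gap was smaller, and 66.6% of border zone-higher and 91.0% of sham-higher regions of day 7 were listed on day 14. In the other order, 64.2% and 62.8% of the regions of day 14 were listed on day 7. Differential regions of day 4 were in both directions listed less often on the later days than its non-differential regions. On day 7 these were 27.2% of border zone-higher, 33.2% of sham-higher and 53.0% of non-differential regions of day 4, and on day 14 32.6%, 39.1% and 64.5%. A region missing from a list need not be closed, because regions below the tag minimum of a day were not listed.

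**Figure D4:**
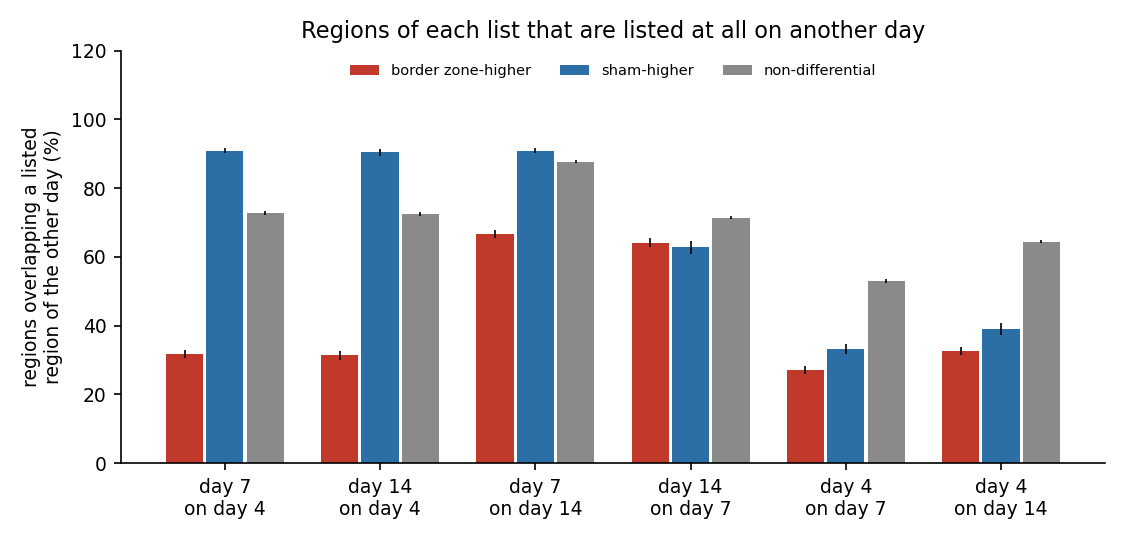
Bars give the percentage of border zone-higher (red), sham-higher (blue) and non-differential (grey) regions of one day that overlap any listed region of another day, with exact 95% binomial intervals. Of the border zone-higher regions of days 7 and 14, 31.9% and 31.4% meet a listed region of day 4, against 91.0% and 90.4% of the sham-higher regions.

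Chromosome X held similar shares of both directions on days 4 and 7. It held 1.43% of border zone-higher regions (1.14 to 1.78%) and 1.33% of sham-higher regions (0.977 to 1.77%) on day 4, and 0.948% (0.720 to 1.22%) and 1.03% (0.813 to 1.28%) on day 7. On day 14 it held 0.636% of border zone-higher regions (0.444 to 0.884%) and 1.63% of sham-higher regions (1.19 to 2.17%), against 0.929% of non-differential regions (0.828 to 1.04%).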

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

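The tests of the explanations in this part were chosen after the results were seen, and the overlap rule of midpoints within 250 bp that one of them uses was set before. Some loci differed from sham in opposite directions on different days. Their number was 213 on days 4 and 7, 133 on days 4 and 14, and 65 on days 7 and 14. Of the 213, 135 were border zone-higher on day 4 and sham-higher on day 7, where independent calls would give 494, and 78 went the other way, where 100 would be given. On days 4 and 14, 38 loci went from border zone-higher to sham-higher (175 for independent calls) and 95 from sham-higher to border zone-higher (86.4). On days 7 and 14 the numbers were 2 (258) and 63 (896). With 1 library per condition and day, none of these differences between days was tested.

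Among loci listed on all 3 days, 31 were sham-higher on day 4 and border zone-higher on both later days, and 18 were border zone-higher on day 4 and sham-higher on both later days. The difference was again not tested. The clearest of the first kind, chosen after its values were seen, was at 194648251 to 194650250 of chromosome 1. Sham was 2.30-fold higher on day 4, with 38 sham tags against 16.6 scaled border zone tags, and the border zone was 2.80-fold higher on day 7 and 2.41-fold higher on day 14. The clearest of the second kind was at 17524251 to 17525750 of chromosome 10, with the border zone 1.60-fold higher on day 4 and sham 1.82-fold higher on both day 7 and day 14. Its day 4 value joins a border zone-higher region with a non-differential one, whose border zone tags are not scaled, and lies below the 1.75-fold of a listed difference.

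Directions on day 4 matched those of the later days less often than days 7 and 14 matched each other, 84.2% for days 4 and 14 against 98.2%. Among 510 loci with at least 100 tags on day 4 the share was 85.7% (82.3 to 88.6%), still below 98.2% (97.7 to 98.6%). These tags are summed over all regions of a locus, so a thinly covered call can pass this limit. It therefore does not decide whether counting noise in thinly covered regions of day 4 is the whole cause. In the upper part of regions by tags on both days, from the median upward, the share was 94.8% of 96 loci for days 4 and 14 (88.3 to 98.3%). This interval reaches that of all loci of days 7 and 14, though not that of days 7 and 14 under the same selection, 99.3% (98.6 to 99.7%). A part of thin coverage in the gap with day 14 stays open. For days 4 and 7 the share in the upper part was 87.2% of 172 loci (81.3 to 91.8%). Of the loci with at least 100 tags and at least 2-fold different on day 4, 94.9% of 196 had the same direction (90.8 to 97.5%), so disagreement was rarer among these stronger calls. This selection was not applied to days 7 and 14. With a fold of at least 2 on both days, 89.7% of loci of days 4 and 14 had the same direction, against 99.2% for days 7 and 14. Wide regions that meet several regions of another day are not the whole cause, because regions with midpoints within 250 bp gave 90.8% for days 4 and 14, against 99.5% for days 7 and 14 by the same rule. The isolation of nuclei and the aligner, which differed between day 4 and the later days, cannot be told apart from a biological change with time after infarction, since 0 days had both kinds of isolation, and the biological explanation stays untested.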

How the results depend on the processing

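The ATAC-seq libraries were paired by day. The RNA-seq groups, which share replicate numbers, were not analysed here, paired or unpaired. Of 173 values from alternative settings for 33 results, 84 stayed within the counting interval or within 1.5 times the count, 86 moved beyond it and 3 turned direction. The cause of these changes was not tested unless stated. Promoter shares, gene lists and motif shares under their alternatives were not run for lack of an mm9 reference. Scaling with 1 factor, a fold of at least 2, an expectation matched on tags, leaving out chromosome Y and unplaced contigs and the test with day as a block were chosen after seeing the data; leaving out these chromosomes moved no result beyond its interval. Regions below the tag minimum of a day carry no values, which limits every setting, and rescaled calls can be made only among listed regions.

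The test over the 3 days with day as a block called 1516 border zone-higher and 457 sham-higher loci in edgeR. Without TMM, with the summed tags of the 19733 loci listed on all 3 days as library sizes, these were 1099 and 459. Without day 4 they were 3073 and 2140, without day 7 950 and 128, and without day 14 551 and 20. DESeq2 gave 1024 and 114. Without the day block edgeR gave 0 and 0, with 584 loci at an unadjusted p under 0.05. The direction of the larger number was kept wherever loci were called. All these settings normalized the libraries on the same loci, those listed on all 3 days. The kept direction therefore does not show that the majority is independent of this normalization. Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 1973 calls in edgeR and the highest of the other splits 0. However, 10 splits are too few for a share under 0.05. Only some of the splits part the sham and border zone libraries of every day as the real one does. With the pairing by day, still fewer splits are therefore comparable with it.

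The border zone share of differential regions on days 4, 7 and 14 was 76.3%, 36.6% and 54.8% in the upper part of regions ranked by whole tags, from the median upward. By covered length it was 63.4%, 43.4% and 68.0%, and with a fold of at least 2 it was 68.6%, 45.9% and 74.4%. With 1 median factor per day it was 63.8%, 56.5% and 62.9%, which turned the majority on day 7, and with 1 factor from the listed tags it was 65.7%, 49.1% and 65%. On days 4 and 14 the border zone stayed in the majority under these settings.

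The share of regions listed on an earlier day fell with stricter overlap. With 50% reciprocal overlap, 58.7% of day 7 and 61.5% of day 14 regions were listed on day 4, and 65% of day 14 regions on day 7. With midpoints within 250 bp these were 53.5%, 56.9% and 60.8%. In the upper part by tags, the shares listed on day 4 were 68.4% and 70.3%.

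The ratio of observed to expected shared border zone-higher loci stayed above 1 throughout. For days 4 and 7, 4 and 14, and 7 and 14 it was 5.18, 5.64 and 4.60 with reciprocal overlap, 6.82, 8.10 and 5.17 with midpoints within 250 bp, 7.23, 8.58 and 6.75 in the upper part by tags, and 7.27, 7.17 and 5.95 with a fold of at least 2. The median factor gave 4.77 for days 4 and 14. An expectation matched on tags gave 2.87 for days 4 and 7 and 3.16 for days 4 and 14.

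For sham-higher loci the ratio fell below 1 in 1 setting. Midpoints within 250 bp gave 0.916 for days 4 and 7 and 1.11 for days 4 and 14, both inside the random sets of matched width, and 1.94 and 2.10 with an expectation matched on tags. The numbers also lay inside these random sets with reciprocal overlap for days 4 and 7 (318, highest 335), with a fold of at least 2 for days 4 and 7 (148, highest 158) and days 4 and 14 (39, highest 42), and with 25% of the shorter region for days 4 and 14 (172, highest 175). In the upper part by tags the 25 loci of days 4 and 14 equalled the highest random set. The upper part by tags gave 1.58, 2.97 and 3.17 for the 3 pairs. A fold of at least 2 gave 1.67 for days 4 and 14 and 3.90 for days 7 and 14. The median factor gave 1.27 for days 4 and 7 and 3.39 for days 7 and 14, and matching on tags gave 1.45 and 1.63 for the pairs with day 4.

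Agreement of direction rose under stricter settings. For the 3 pairs it was 88.9%, 90.8% and 99.5% with midpoints within 250 bp, 87.2%, 94.8% and 99.3% in the upper part by tags, and 90.1%, 89.7% and 99.2% with a fold of at least 2. Reciprocal overlap gave 98.9% for days 7 and 14, and the median factor gave 85.3% for days 4 and 7 and 98.9% for days 7 and 14.

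The 297 loci border zone-higher on all 3 days became 31 in the upper part by tags and 160 with a fold of at least 2. The 115 sham-higher loci became 26 with midpoints within 250 bp, 10 in the upper part by tags and 25 with a fold of at least 2. Fewer regions enter these lists by construction. Without day 4 the counts were 2208 and 1308.

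The share of regions with a same-direction neighbour, divided by the permuted median, was 1.13, 1.12 and 1.29 for border zone-higher and 1.13, 1.15 and 0.956 for sham-higher regions on days 4, 7 and 14. Within 10 kb it was 1.29, 1.29 and 1.51, and 1.37, 1.47 and 1.16, so sham-higher regions of day 14 crossed 1, inside the permuted range at both distances. Within 200 kb it was 1.02, 1.02 and 1.09, and 1.05, 1.02 and 0.936 for sham-higher regions. At this distance border zone-higher regions of day 7 and sham-higher regions of days 4 and 14 lay inside the permuted range. With regions within 2 kb merged, border zone-higher regions of day 14 gave 1.32. Of the 5 named windows per direction, 4 or 5 met a leading window when the grid was shifted by 50 kb or the windows were 250 kb wide.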

Other observations

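All tests and examples in this part were chosen after the results were seen. The 5 widest sham-higher regions of day 7 were each listed as 1 region of at least 10.5 kb. The span of the widest, on chromosome 5, held 14 listed regions on day 4 and 18 on day 14. After the 41.0-kb region of chromosome 5 described above came 76718251 to 76740750 of chromosome 2, 22.5 kb wide, where sham was 2.39-fold higher (2.25 to 2.55), and 76745251 to 76758750 of the same chromosome, 13.5 kb wide, at 2.23-fold (2.05 to 2.43). A region of 11 kb at 43185251 to 43196250 of chromosome 1 was 2.56-fold higher in sham (2.34 to 2.81) and overlapped 0 listed regions on day 4 and day 14. A region of 10.5 kb at 76843751 to 76854250 of chromosome 15 was 2.31-fold higher in sham (2.17 to 2.46). Summed over all listed regions inside these spans, sham was 1.42-fold and 1.54-fold higher on days 4 and 14 at the chromosome 5 span, and 1.41-fold on both days at the chromosome 15 span. At the 2 spans of chromosome 2 it was 1.16-fold and 1.38-fold higher, and 1.16-fold and 1.19-fold. Day 4 listed 0 sham-higher and 0 border zone-higher regions in either of them. Their day 4 folds thus rest on non-differential regions alone, whose border zone tags are not scaled. The listed regions of day 4 carried more sham than border zone tags in total, so these 1.16-fold values do not show a difference at these spans. The day 4 folds of the chromosome 5 and 15 spans also include such unscaled regions. Regions of at least 5 kb numbered 42 among sham-higher and 28 among border zone-higher regions on day 7, against 2 and 9 on day 14 and 2 and 6 on day 4. These were 0.545% of sham-higher and 0.458% of border zone-higher regions on day 7. Non-differential regions of this width numbered 57 on day 7, 75 on day 14 and 175 on day 4, which is 0.270%, 0.229% and 0.465% of the non-differential regions.

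At the 5527 loci that were sham-higher on day 7 and did not differ on day 14, the border zone tags differed between the days more than the sham tags. Border zone tags there had a median log2 ratio of day 7 to day 14 of -0.53 relative to all loci shared by the 2 days, and sham tags had one of -0.02. At the 1808 loci border zone-higher on day 7 and not different on day 14, the medians were 0.63 for border zone and -0.08 for sham tags. Both sets were chosen by their ratios on the 2 days, so a shift of border zone relative to sham tags is built in. The border zone library of day 7 also had the fewest tags in listed regions, 2743793, and selection on its counting noise would move it most. These medians therefore do not tell which library changed. Over the 19733 loci listed on all 3 days, sham and border zone tags of one day correlated with a Spearman coefficient of 0.95 on day 4, 0.78 on day 7 and 0.88 on day 14, and the sham libraries of days 7 and 14 correlated at 0.82. The border zone library of day 7 had the lowest coefficient of any library with sham day 4 (0.34), border zone day 4 (0.38) and sham day 14 (0.61), and 0.78 with border zone day 14. Sham day 7 had 0.65 and 0.62 with the day 4 libraries. The values of day 7 above thus rest on 1 border zone library, which stands apart from the day 4 libraries and from sham day 14. Border zone day 14 was also low with day 4, at 0.50 with sham and 0.53 with border zone. Counting noise lowers such coefficients, and most so in the library with the fewest tags. These coefficients are across loci, which are not independent.

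Regions on unplaced contigs and chromosome Y leaned to the border zone on the later days. On day 7, 64 of 131 regions on unplaced contigs other than those of chromosome Y were border zone-higher and 6 were sham-higher, with a median log2 ratio of 0.93 relative to all regions. On day 14 the numbers were 23 and 1 of 82, with a median of 0.30. Of 29 regions on chromosome Y and its contigs on day 14, 24 were border zone-higher and 0 were sham-higher. Whether these regions are repeated sequence, where reads map to several places, was not examined.

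A pattern for follow-up is the excess of sham-higher regions on day 7, when the border zone share was 44.3%. Whether it comes from the factors that scale the border zone tags cannot be told from rescaling, because a larger factor raises the share by construction. The share was 56.5% with 1 median factor per day and 49.1% with 1 factor from the listed tags. Day 14 tags thinned to the day 7 total, with the tag minimum of day 7, kept a border zone share of 61.5%. Both libraries were thinned by the same fraction, which keeps their ratio and adds noise in both directions. The share could therefore hardly fall below 50% this way. Thinning does not decide whether the smaller number of tags on day 7 is the cause. A larger loss of accessibility in the border zone on day 7 than on day 14 stays open as a biological explanation and was not tested, since each day has 1 library per condition. A peculiarity of the single border zone library of day 7, described above, stays open as well.

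Another pattern is that 31.9% of day 7 and 31.4% of day 14 border zone-higher regions were listed on day 4, against over 90% of sham-higher regions. Non-differential regions of matched tags were listed on day 4 more often, in 62.5% of cases for day 7 and 53.4% for day 14. This matching does not settle whether few sham tags are the cause. Border zone-higher regions had a median of 34 sham tags on day 7 and 97 on day 14, against 72 and 239 in non-differential regions. Few sham tags therefore stay open as a cause. Contigs that the day 4 lists lack do not explain the pattern, since the share of day 14 regions on chromosomes 1 to 19 and X was 31.6%. The change in the isolation of nuclei cannot be told apart from chromatin that opened in the border zone only after day 4, because 0 days had both kinds of isolation. Both stay open. The regions of day 4 that differed were also listed less often on the later days than its non-differential regions, in both directions.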
